A study of Mus musculus with 8 samples.

How the data were processed

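Liver total RNA of 8 female C57/BL6 mouse samples was measured on Illumina bead arrays, 1 array for each combination of diet (5% or 21% corn oil w/w), age (90 or 456 days) and generation (F1 or F3). Per the labels' protocols, RNA was extracted with Trizol, its quality was checked on an Agilent Bioanalyser and it was labelled with biotin. The deposited values are intensity on a linear scale, 1 value per probe and array. The authors' normalization method is not given in the sources used here. The arrays had nearly equal means and medians, and their sorted values differed by at most 7.25%, so the values had been normalized between arrays before deposition. The lowest value was 101.4 and the highest 30694, so no background had been subtracted. Detection p-values, raw scanner files and sample pairing by animal were not used here.

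The values were used as deposited and log2 transformed. Of 25697 probes, 23978 carried 1 gene symbol, 0 carried several and 1719 carried none. Symbols were checked against a gene table of assembly GRCm38.p6, used only for names, and 0 changed. Probes with a mean log2 intensity above 6.95, the median of the probe means, were kept (12848 probes, 12096 with a symbol), and each gene was represented by its probe with the highest mean, which left 8945 genes. Of these, 2285 had more than 1 kept probe.

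Gene differences were tested with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), by an additive linear model of diet, age and generation with 4 residual degrees of freedom, moderated variances with an intensity trend (4.36 prior degrees of freedom), and Benjamini-Hochberg adjustment over all genes for each factor. All tests were two-sided and the threshold was an adjusted p of 0.05. Each interaction was tested by adding its term to that model (3 residual degrees of freedom). With 1 array per combination the error was taken from the additive model, so any real interaction adds to it.

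Genes were grouped into 44 lists, each fixed before the data were examined, and lists were matched by symbol. Of 1208 list symbols, 873 were measured. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. No list passed for any factor with an estimated correlation (smallest adjusted p 0.385 for diet, 0.442 for age, 0.778 for generation) or with fry (0.143, 0.0903 and 0.936). Each member was also adjusted over the list alone.

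Groups, comparisons, tests, alternatives, lists and the rule for named genes were fixed before the data were examined. By that rule the genes named for each factor were the 10 with the largest difference in each direction among those that passed and had the same sign in all 4 matched pairs. Open places went to the genes with the smallest p and the same sign in 4 pairs, reported as not passing. For each list described, 2 to 4 members with the largest absolute difference were named, and how many of them was settled when the text was written. For each interaction the 3 genes with the smallest p were named. Genes of the sex chromosomes, of skeletal muscle, stomach and islets, and acute phase genes read on single arrays were chosen after their values were seen.

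The alternatives planned were other scalings of the arrays, raising low values to a floor, no filter or a stricter one, other ways to combine probes, other variance models, other thresholds, other designs and leaving out each array in turn. Background subtraction (the 5th percentile of each array, plus a pseudocount of 16), array weights and the pancreas marker level as a covariate were added after the data had been seen. When 1 array was left out its combination had none, and the fit had 3 residual degrees of freedom.

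The procedure was tested on simulated data with 200 changed genes in each of 5 runs. Variances were drawn from the prior that limma fitted to these arrays, not taken gene by gene. Of genes changed by 1 on the log2 scale it recovered 98.5% for diet, 97.3% for age and 97.3% for generation, and 60.0%, 57.9% and 57.6% for the interactions diet by age, diet by generation and age by generation. Of genes changed by 0.5 it recovered 64.2% for diet, 67.5% for age and 67.5% for generation. Genes were simulated as independent, so effects shared between genes, such as tissue carried over into an array, were not part of that test. In the real data Elovl6 by diet (-1.19, adjusted p = 0.389 by limma) and Egfr by age (-1.32, adjusted p = 0.0645 by limma) did not pass. The simulation thus does not rule out missed differences of 1 or more. Figures were drawn with matplotlib 3.10.9.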

Results

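The data were expression profiles of liver total RNA from female C57/BL6 mice of the F1 and F3 generations, taken after a 6 h fast and measured on 8 Illumina bead arrays. Each combination of dietary corn oil (5% or 21% w/w), age (90 or 456 days) and generation (F1 or F3) was measured on 1 array. Every level of a factor had 4 arrays, and no combination had a replicate. The labels did not say whether an array held 1 animal or a pool, nor which animals ate the diets and when. Expression of 8945 genes was tested. Mean intensity was 457 on each array and median intensity was between 123.2 and 123.5. The number of arrays limited the precision, and the median standard error of a difference was 0.08 on the log2 scale. Differences are log2 differences with their standard errors (n = 4 arrays per level) unless stated. They come from intensities without background subtraction, so differences of dim genes are understated. P-values measure only the spread between these arrays, not between animals.

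Transcripts of other tissues were present in some of the liver arrays. The median log2 intensity of 21 pancreas markers, which encode digestive enzymes and their helpers, was 8.88 in the F3 5% D90 array, 9.51 in the F1 5% D456 array and 10.21 in the F3 5% D456 array, against 6.87 in the F1 5% D90 array and 6.89 to 6.98 in the 4 arrays of the 21% diet. Cela2a, a pancreatic elastase, reached an intensity of 4339.9 in the F3 5% D456 array, against 186 to 241 in the 5 arrays without these transcripts. The skeletal muscle genes Acta1 and Myl1 stood at log2 intensities of 9.69 and 9.80 in the F1 5% D90 array and of 9.369 and 9.004 in the F3 5% D456 array, and at 7.60 or less elsewhere. Eif2s3y, a gene of the Y chromosome, had an intensity of 165.7 in the F1 21% D90 array and of 109.2 to 113.1 in the other 7 arrays. Xist, which is transcribed from the inactive X chromosome of female cells, had an intensity of 273.5 in the F1 21% D90 array, within the range of 252.8 to 396.9 of the other 7. These genes of the sex chromosomes were looked at after the other values had been seen. The F1 5% D90 array stood apart from the rest, with a mean correlation of 0.977 with the other arrays, against 0.986 to 0.990 for the others.

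**Figure D1:**
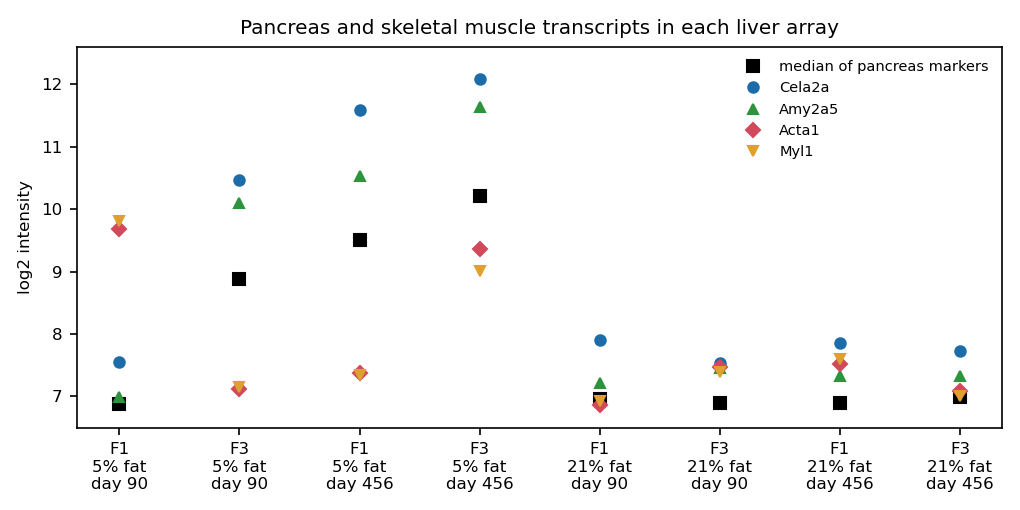
Log2 intensity of pancreas markers (median of 21 genes, black squares), of the pancreatic genes Cela2a and Amy2a5 and of the skeletal muscle genes Acta1 and Myl1 in each of the 8 liver arrays, 1 point per array. The pancreas median is 8.88, 9.51 and 10.21 in 3 arrays of the 5% diet and 6.98 or less in the other 5 arrays.

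Age gave the clearest differences of single genes. Between day 90 and day 456, 6 genes rose. Csprs rose by 0.97 ± 0.09 (from a mean of 7.64 to 8.61, adjusted p = 0.00815), and Slc4a1, the anion exchanger of red blood cells, rose by 0.90 ± 0.08 (from 7.31 to 8.21, adjusted p = 0.00815). Tmem45b rose by 0.70 ± 0.06 (from 7.01 to 7.71) and C130026I21Rik by 0.32 ± 0.03 (from 6.98 to 7.29, adjusted p = 0.00815 for both). Mzb1, a protein of antibody-secreting B lineage cells, rose by 0.54 ± 0.06 (from 7.13 to 7.675, adjusted p = 0.0220). Il1b, the inflammatory cytokine interleukin 1 beta, rose by 0.54 ± 0.07 (from 7.31 to 7.85, adjusted p = 0.0338). At day 90 Slc4a1, Tmem45b, C130026I21Rik, Mzb1 and Il1b were dim, near the filter bound of 6.95. The carboxylesterase Ces3b fell by 1.14 ± 0.14 (from 11.62 to 10.48, adjusted p = 0.0405), the adhesion protein Cdh1 (E-cadherin) fell by 0.96 ± 0.11 (adjusted p = 0.0247), and Cyp1a2, a drug-metabolizing cytochrome P450, fell by 0.73 ± 0.09 (adjusted p = 0.0409). Each of these 9 genes moved the same way in 4 of 4 matched pairs of arrays.

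**Figure D2:**
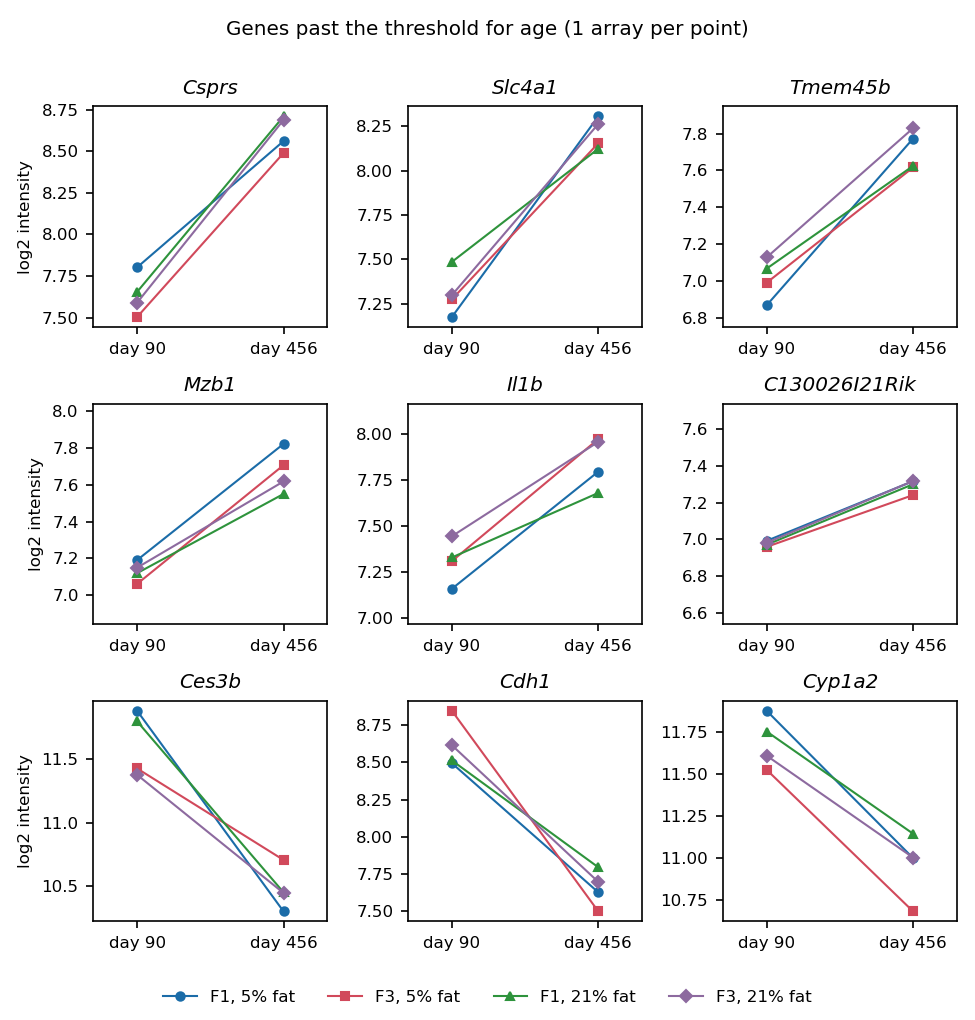
Log2 intensity of the 9 genes past the threshold for age, at day 90 and day 456, 1 array per point. Lines join arrays of the same generation and diet, and in each of the 9 panels all 4 lines run the same way.

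Next to these stood genes that did not pass. Among those higher at day 456 were the sialyltransferase gene St3gal6 (+0.99 ± 0.14, adjusted p = 0.0628), Plekhb1 (+0.66 ± 0.10, adjusted p = 0.0645), the platelet chemokine Ppbp (+0.33 ± 0.05, adjusted p = 0.0530) and Gdf3 (+0.27 ± 0.04, adjusted p = 0.0628). Among those lower were Cyp4f14 (-0.62 ± 0.08, adjusted p = 0.05003), the keratin gene Krt23 (-0.84 ± 0.12, adjusted p = 0.0548), the epidermal growth factor receptor gene Egfr (-1.32 ± 0.20), the chemokine gene Ccl21a (-0.55 ± 0.08), Keg1 (-0.74 ± 0.12) and the complement gene C8b (-1.21 ± 0.19). Serpina1e, an alpha-1-antitrypsin gene, had the largest difference of the genes named for age, -2.50 ± 0.35 (adjusted p = 0.0530).

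Markers of immune and blood cells were higher at day 456. All 11 measured neutrophil markers were higher (median +0.29), and 7 passed when adjusted over the list alone, against 1 over all genes tested. The calprotectin subunits S100a8 (+1.301 ± 0.20) and S100a9 (+0.82 ± 0.12) and the iron-binding lipocalin Lcn2 (+1.53 ± 0.58) had the largest differences. Lcn2 fell with age in F1 with 21% fat (from 11.22 to 10.44). It rose in the other pairs, most in F3 with 21% fat (from 8.40 to 11.89), and is read again with the acute phase genes below. Of 27 markers of Kupffer cells, the resident macrophages of liver, and other macrophages, 23 were higher (median +0.32) and 12 passed when adjusted over the list alone, against 0 over all genes tested (limma). Examples were the lysozymes Lyz2 (+1.41 ± 0.33) and Lyz1 (+0.73 ± 0.11), the complement receptor Vsig4 (+0.79 ± 0.15) and the complement subunit C1qc (+0.72 ± 0.21). Without the F1 5% D90 array, in which Lyz2 deviated by -2.31 from the other arrays, the Lyz2 difference was +0.97 and the macrophage median +0.22. B cell and plasma cell markers were higher in 11 of 11 (median +0.14), with 7 passing when adjusted over the list alone, among them Mzb1 and the B cell receptor subunit Cd79b (+0.31 ± 0.08). All 14 genes of antigen presentation on MHC class II were higher (median +0.17) and 5 passed when adjusted over the list alone. Lgmn (+0.58 ± 0.22), Ifi30 (+0.50 ± 0.14), H2-Eb1 (+0.48 ± 0.13) and Cd74 (+0.47 ± 0.10) led this group. The Lgmn difference was smaller without the F1 5% D90 array. Of 6 red blood cell markers, 5 were higher (median +0.29) and 4 passed when adjusted over the list alone, with Slc4a1, the heme synthesis enzyme Alas2 (+0.56 ± 0.09) and the globin Hba-a1 (+0.45 ± 0.10) in front. T cell and NK cell markers were higher in 9 of 11 (median +0.08), led by the chemokine Ccl5 (+0.52 ± 0.12) and Cd8b1 (+0.20 ± 0.07), and 1 passed when adjusted over the list alone. These 6 lists passed with the preset correlation of 0.01 in limma's camera, and for each the adjusted p = 0.442 with an estimated correlation.

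**Figure D3:**
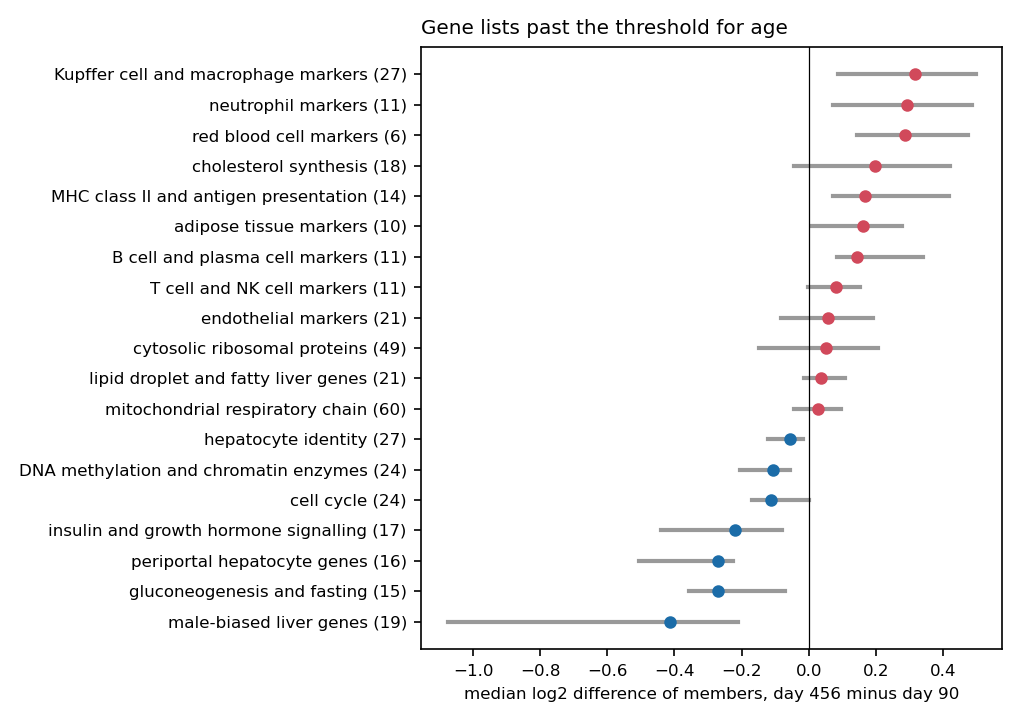
Median log2 difference (day 456 minus day 90) of the members of each gene list past the threshold for age, pancreas markers left off for scale, with the number of measured members in parentheses. Bars run from the lowest to the highest of the medians in the 4 matched pairs. Kupffer cell and macrophage markers (+0.32) and male-biased liver genes (-0.41) mark the ends.

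Male-biased liver genes, which are expressed more in male than in female liver, were lower in 16 of 19 (median -0.41), and 10 passed when adjusted over the list alone, 1 of them higher. Serpina1e, the cytochrome P450 gene Cyp2d9 (-1.88 ± 0.33), the steroid dehydrogenase gene Hsd3b5 (-1.72 ± 0.45) and the urinary protein gene Mup21 (-1.21 ± 0.32) had the largest differences. These 4 genes were highest in the F1 21% D90 array, the array with the Eif2s3y signal, and without that array their differences were -2.05, -1.45, -1.08 and -0.77 and the list median -0.29. Periportal hepatocyte genes were lower in 14 of 16 (median -0.27), with 7 passing when adjusted over the list alone, among them Cdh1, the histidine-degrading enzyme gene Hal (-0.60 ± 0.10) and Cyp2f2 (-0.48 ± 0.10), while the urea cycle gene Asl had a difference of the other sign (+0.52 ± 0.31). It was at +0.15 without F1 5% D90 and at +0.22 without F1 5% D456. Genes of gluconeogenesis and fasting were lower in 13 of 15 (median -0.27), 5 of which passed when adjusted over the list alone. They included Pck1 (-0.45 ± 0.08) and G6pc (-0.41 ± 0.12), enzymes of glucose production, and the insulin signalling adaptor Irs2 (-0.44 ± 0.12). In insulin and growth hormone signalling 13 of 17 were lower (median -0.22) and 4 passed when adjusted over the list alone, led by Egfr, the binding protein gene Igfbp2 (-0.69 ± 0.13) and the growth hormone feedback gene Socs2 (-0.64 ± 0.13). The median of this list was -0.142 without F1 21% D90 and -0.144 without F1 5% D456. With an estimated correlation the adjusted p = 0.456 for the male-biased genes and 0.442 for the other lists of this paragraph.

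Cholesterol synthesis genes were higher in 14 of 18 (median +0.20), with Fdps (+0.78 ± 0.21) and Nsdhl (+0.69 ± 0.25) in front and 0 passing by limma when adjusted over the list alone. The median of this list was +0.117 without F1 21% D456, +0.118 without F1 21% D90 and +0.299 without F3 21% D456. Nsdhl was at +0.41 without F1 5% D90 and at +0.38 without F1 5% D456. Genes of lipid droplets and fatty liver (median +0.04, 14 of 21 higher, 5 passing when adjusted over the list alone) and adipose tissue markers (median +0.16, 8 of 10 higher, 2 passing) shared the droplet protein gene Plin4 (+0.68 ± 0.19) and the adipogenic receptor gene Pparg (+0.41 ± 0.08), beside Plin2 (+0.54 ± 0.17) and Thrsp (+0.45 ± 0.31). The adipose median was +0.0935 without F1 5% D90 and +0.105 without F1 5% D456. Cell cycle genes were lower in 20 of 24 (median -0.11), among them Cdca3 (-0.43 ± 0.13) and Cdc20 (-0.41 ± 0.12). Hepatocyte identity genes were lower in 24 of 27 (median -0.06), with Hal and Alb, the albumin gene (-0.38 ± 0.10), in front. Genes of DNA methylation and chromatin enzymes were lower in 21 of 24 (median -0.11), led by the histone methyltransferase gene Ehmt2 (-0.25 ± 0.11) and the acetyltransferase gene Ep300 (-0.25 ± 0.15). Endothelial markers were higher in 14 of 21 (median +0.06), led by Fcgr2b (+0.39 ± 0.13) and Plvap (+0.24 ± 0.09). Genes of the mitochondrial respiratory chain (median +0.03, 37 of 60 higher) were led by the ATP synthase genes Atp5pb (+0.66 ± 0.37) and Atp5l (+0.32 ± 0.17). Genes of cytosolic ribosomal proteins (median +0.05, 38 of 49 higher) were led by Rps6 (+0.70 ± 0.37) and Rps7 (+0.63 ± 0.38). Without the F1 5% D90 array, in which Atp5pb, Rps6 and Rps7 were low, these differences were +0.18, +0.12, +0.20 and +0.11, in the order given. Pancreas markers were higher in 21 of 21 (median +1.04; Cela2a +1.45 ± 0.66, Clps +1.43 ± 0.55), and 0 passed by limma when adjusted over the list alone. Their median was +0.49 without the F1 5% D90 array. With an estimated correlation the adjusted p = 0.442 for adipose tissue markers, 0.522 for endothelial markers and 0.456 for the other lists of this paragraph.

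By limma 9 of 8945 genes passed for age, with 1091 at an unadjusted p below 0.05, and 19.4% of genes had the same sign in all 4 pairs, where chance gives 12.5%. Genes are correlated, so such a share can stray from 12.5% without an effect of age. Age differences of the F1 pair with 21% fat had correlations of -0.05 to 0.01 with the other pairs. Those had 0.33 to 0.61 among themselves, highest between the pairs with 5% fat, whose arrays of day 456 held pancreas transcripts. Leaving out 1 array gave 0 genes without F3 5% D90, F3 21% D90 or F3 21% D456, 4 without F1 5% D456, 6 without F3 5% D456 (5 of the 9 among them), 7 without F1 21% D456, 19 without F1 21% D90 and 23 without F1 5% D90. Of 44 lists, 20 passed for age (13 higher, 7 lower) and none did with an estimated correlation, and 14 of the 20 passed in each of the 8 fits without 1 array. The other 6 did not pass in every such fit: endothelial markers (highest adjusted p = 0.290, without F3 5% D90), respiratory chain (0.323, without F1 5% D90), DNA methylation and chromatin enzymes (0.107, without F3 21% D456), lipid droplets (0.0746, without F3 21% D456), cell cycle (0.0676, without F3 21% D456) and hepatocyte identity (0.0656, without F3 5% D90). Over the 8 fits their medians ranged from 0.0067 (without F3 5% D90) to 0.127 for endothelial markers, from 0.0062 (without F1 5% D456) to 0.0483 for the respiratory chain and from 0.0051 (without F3 21% D456) to 0.102 for lipid droplets. The ranges were -0.117 to -0.0479 (without F1 5% D90) for chromatin enzymes, -0.141 to -0.0558 (without F3 21% D90) for cell cycle and -0.0720 to -0.0415 (without F1 5% D456) for hepatocyte identity. Of the lists that passed in each fit, ribosomal proteins ranged from 0.0337 (without F1 5% D90) to 0.112 (without F1 21% D456), and T cell and NK cell markers reached 0.127 without F3 21% D90.

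Diet was compared as 21% fat against 5% fat. All 19 measured genes of fatty acid and triglyceride synthesis were lower with 21% fat than with 5% fat (median -0.19), 9 of them in 4 of 4 pairs. The median was -0.32 without the F1 5% D90 array. Elovl6, which elongates fatty acids, had a difference of -1.19 ± 0.22 (from a mean of 11.33 to 10.14), Acaca, which makes the building block of fatty acids, of -0.84 ± 0.17, Scd1, the main desaturase of liver, of -0.74 ± 0.14 and Acss2, which activates acetate, of -0.63 ± 0.23. In this list 4 genes passed when adjusted over the list alone and 0 over all genes tested (limma). The list passed in limma's camera with an adjusted p = 1.09e-11 at the preset correlation and an adjusted p = 0.447 with an estimated correlation. Genes of mitochondrial fatty acid oxidation were higher with 21% fat in 17 of 17 (median +0.14), with Etfdh (+0.31 ± 0.17), which passes electrons from fat oxidation to the respiratory chain, and Acadm (+0.27 ± 0.08), a dehydrogenase of medium-chain fatty acids, in front. Without the F1 5% D90 array Etfdh was at +0.10. With all arrays the second probe of Etfdh had a difference of +0.01 and that of Acadm of +0.10. The median intensity of the list in F1 5% D90 was 11.43, inside the 11.325 to 11.602 of the 4 arrays of the 21% diet. The 3 arrays of the 5% diet with pancreas transcripts had 11.196 to 11.211. The median difference was above 0 in 4 of 4 pairs, by 0.05 in the lowest. None of these 17 passed by limma when adjusted over the list alone, and the adjusted p = 0.385 for the list with an estimated correlation. Genes that desaturate and elongate polyunsaturated fatty acids were lower in 9 of 12 (median -0.09, adjusted p = 0.639 with an estimated correlation), led by Cyb5r3 (-0.42 ± 0.11) and Elovl2 (-0.36 ± 0.19), and 1 passed when adjusted over the list alone.

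**Figure D4:**
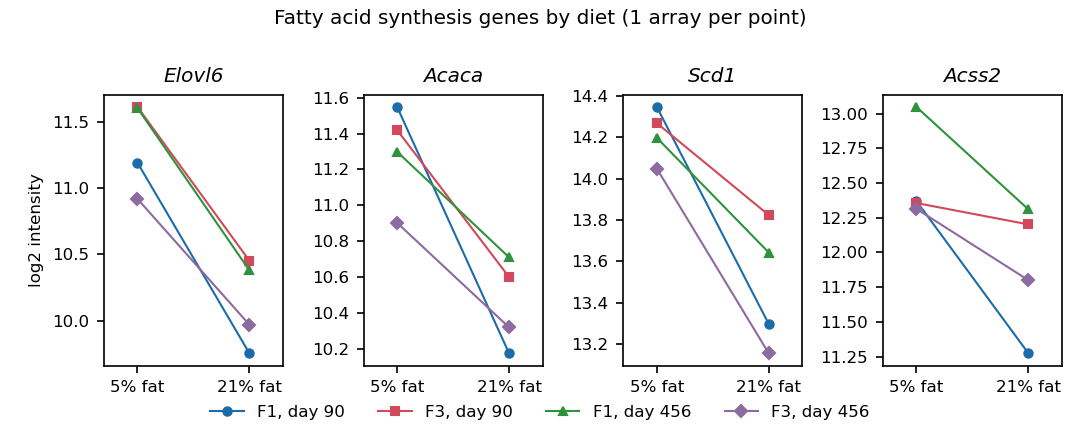
Log2 intensity of Elovl6, Acaca, Scd1 and Acss2, the 4 fatty acid synthesis genes with the largest diet differences, with 5% and 21% fat, 1 array per point. Lines join arrays of the same generation and age, and all 4 lines fall in each panel.

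No single gene passed for diet. Of the genes with the smallest p-values, higher ones were the sulfotransferase gene Sult5a1 (+0.54 ± 0.07) and the dehydrogenase gene Sdr9c7 (+0.52 ± 0.07, adjusted p = 0.161 for both), Ugt3a1 (+0.54 ± 0.08), the immediate early transcription factor gene Egr1 (+1.01 ± 0.16) and Csad, an enzyme gene of taurine synthesis (+0.79 ± 0.12), the last of these with an adjusted p = 0.211, as for Ugt3a1 and Egr1. Also higher were Gm4952 (+0.52 ± 0.11), the serum amyloid gene Saa4 (+0.47 ± 0.10), Upk3b (+0.27 ± 0.06), Dpm1 (+0.15 ± 0.03) and Tpm2 (+0.33 ± 0.08), whose second probe had a difference of -0.49. Lower ones were the phospholipid transfer protein gene Pltp (-0.74 ± 0.10), the axon guidance receptor gene Robo1 (-0.83 ± 0.13) and Evc2 (-0.18 ± 0.03), each with an adjusted p = 0.211. Pdzk1ip1 (-0.85 ± 0.15), Acpp (-0.80 ± 0.16), Gal3st1 (-0.25 ± 0.04) and Acin1 (-0.24 ± 0.05, second probe +0.01) followed, beside Elovl6 (adjusted p = 0.389), Scd1 (adjusted p = 0.483) and Acaca (adjusted p = 0.567).

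Pancreas markers were lower with 21% fat in 21 of 21 (median -1.94), since 3 arrays of the 5% diet held them and none of the 21% diet did. Cela2a (-2.66 ± 0.66), Amy2a5 (-2.48 ± 0.61) and Clps (-2.44 ± 0.55) had the largest differences, 20 passed when adjusted over the list alone, and the adjusted p = 0.447 for the list with an estimated correlation. Male-biased liver genes were higher with 21% fat in 17 of 19 (median +0.24), with Cyp7b1 (+0.98 ± 0.31) and Hsd3b5 (+0.63 ± 0.45) in front. Without the F1 21% D90 array, which had the Eif2s3y signal, this list had a median of +0.03 and an adjusted p = 0.351, Cyp7b1 was at +0.56 and Hsd3b5 at -0.01. With all arrays the adjusted p = 0.639 for the list with an estimated correlation. Genes of glycolysis and glucose uptake were lower in 11 of 14 (median -0.03), and both Pklr, a pyruvate kinase gene (-0.31 ± 0.08), and Ldha, a lactate dehydrogenase gene of the other sign (+0.33 ± 0.09), passed when adjusted over the list alone (adjusted p = 0.468 for the list with an estimated correlation). Genes of gluconeogenesis and fasting (11 of 15 lower, median -0.06, adjusted p = 0.706 with an estimated correlation) and periportal genes (12 of 16 lower, median -0.05, adjusted p = 0.757 with an estimated correlation) shared G6pc (-0.38 ± 0.12) and Pck1 (-0.24 ± 0.08), and Alb (-0.40 ± 0.10) led the periportal genes. MHC class II genes were lower in 12 of 14 (median -0.05; H2-Aa -0.29 ± 0.13, Cd74 -0.21 ± 0.10) and T cell and NK cell markers in 10 of 11 (median -0.07; Ccl5 -0.20 ± 0.12, Cd8b1 -0.15 ± 0.07), with an adjusted p = 0.757 and an adjusted p = 0.639 with an estimated correlation. Endothelial markers were higher in 15 of 21 (median +0.10; Mrc1 +0.28 ± 0.13, Clec4g +0.22 ± 0.09, adjusted p = 0.706 with an estimated correlation). Heat shock proteins were higher in 12 of 16 (median +0.12; Hspb1 +0.41 ± 0.11, Hsph1 +0.30 ± 0.23) and proteasome genes in 24 of 27 (median +0.10; Psma5 +0.21 ± 0.08, Psmd13 +0.21 ± 0.11), with an adjusted p = 0.757 and an adjusted p = 0.468 with an estimated correlation.

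By limma 0 genes passed for diet, with 288 at an unadjusted p below 0.05 and a smallest adjusted p = 0.161, and 10.1% of genes had the same sign in all 4 pairs, where chance gives 12.5%. Without the F1 5% D90 array, the only array of the 5% diet without pancreas transcripts, 30 genes passed, 18 of them pancreas markers. Of the 12 others, 4 were further genes expressed in pancreas and lower with 21% fat, Gm5409 (-2.08), Gm5771 (-1.56), Pla2g1b (-0.99) and Klk1 (-0.87). The rest were Egr1, Sult5a1, Sdr9c7, Csad, Cyp4a14, Retsat, Pltp and Evc2. Of 44 lists, 13 passed for diet (5 higher, 8 lower) and none with an estimated correlation. Fatty acid synthesis, mitochondrial fatty acid oxidation, pancreas markers and proteasome passed in each of the 8 fits without 1 array. With the pancreas marker level as a covariate, chosen after the data were seen, none of them passed (adjusted p = 0.264, 0.0545, 0.865 and 0.716, in that order). That level was high in 3 arrays of the 5% diet only, so the covariate takes up part of the diet difference. The lost calls thus do not show that pancreas tissue accounts for it. In F1 5% D90 the median intensity of fatty acid synthesis genes was 10.67, above the 10.045 to 10.379 of the 21% diet. That of fatty acid oxidation was 11.43, inside the 11.325 to 11.602 of the 21% diet. Over all alternatives the highest adjusted p was 0.447, 0.385, 0.865 and 0.716. The other 9 did not pass in each of the 8 fits without 1 array: gluconeogenesis (highest adjusted p = 0.432, without F3 5% D90), male-biased genes (0.351, without F1 21% D90), periportal genes (0.329, without F3 5% D90), MHC class II and heat shock (0.308 for both, without F3 5% D456), endothelial markers (0.199, without F3 5% D90), glycolysis (0.102, without F3 21% D456), polyunsaturated fatty acid genes (0.0832, without F1 21% D90) and T cell and NK cell markers (0.0658, without F3 21% D456). Over the 8 fits the medians of all 9 of these lists moved by more than 1.5 times in at least 1 fit. They ranged from -0.114 (without F1 21% D456) to -0.0147 (without F3 5% D90) for gluconeogenesis and from -0.115 (without F1 21% D456) to -0.0026 (without F3 5% D90) for periportal genes. MHC class II ranged from -0.104 (without F1 21% D90) to -0.0228 (without F1 21% D456), glycolysis from -0.0647 (without F1 5% D456) to -0.0331 and male-biased genes up to 0.388 (without F1 21% D456). The smallest sizes were +0.0499 for heat shock (without F3 5% D456), +0.043 for endothelial markers (without F3 21% D90), -0.0485 for polyunsaturated fatty acid genes (without F1 21% D90) and -0.0385 for T cell and NK cell markers (without F3 21% D456).

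Between the generations, no gene passed. Among the genes with the smallest p-values, Csad had the largest difference (+0.74 ± 0.12, higher in F3). It was followed by Ubd (+0.45 ± 0.13), Tnfrsf12a (+0.43 ± 0.11), the cytochrome P450 gene Cyp2b9 (+0.30 ± 0.08), Cbr3 (+0.29 ± 0.07), the epoxide hydrolase gene Ephx1 (+0.27 ± 0.08), Brix1 (+0.26 ± 0.08), Rtn4 (+0.25 ± 0.08), Mmp13 (+0.15 ± 0.04) and Phlda3 (+0.10 ± 0.03). Lower in F3 were Pdcd4 (-0.58 ± 0.16), Ttc39c (-0.39 ± 0.12), the vitamin A storage gene Lrat (-0.31 ± 0.10), Alas2 (-0.30 ± 0.09), Pdk2 (-0.27 ± 0.09), Tbc1d16 (-0.14 ± 0.04), Pdxk (-0.13 ± 0.04), 1700029I15Rik (-0.12 ± 0.03), Cyp26b1 (-0.09 ± 0.02) and Cbx3 (-0.07 ± 0.02). For each of them the adjusted p = 0.988.

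As groups, pancreas markers were higher in F3 in 21 of 21 (median +0.65; Reg1 +1.18 ± 0.49, Amy2a5 +1.11 ± 0.61), and male-biased genes were lower in 16 of 19 (median -0.31; Cyp4a12a -0.52 ± 0.39, Cyp2d9 -0.45 ± 0.33). Without the F1 21% D90 array, the one with the Eif2s3y signal, the male-biased list had a median of -0.00077 and an adjusted p = 0.432, with Cyp4a12a at +0.04 and Cyp2d9 at -0.03. Without the F1 5% D90 array the pancreas list had a median of +0.08 and an adjusted p = 0.284. Macrophage markers were higher in 18 of 27 (median +0.08; Lyz2 +0.63 ± 0.33, Gpnmb +0.43 ± 0.19) and MHC class II genes in 12 of 14 (median +0.09; H2-Ab1 +0.21 ± 0.14, Lgmn +0.20 ± 0.22). Also higher were cell cycle genes in 20 of 24 (median +0.04; Cdca3 +0.33 ± 0.13, Cdc20 +0.27 ± 0.12) and proteasome genes in 18 of 27 (median +0.06; Psmb7 +0.45 ± 0.24, Psma5 +0.20 ± 0.08). Lyz2 was at +0.19, Psmb7 at +0.13 and Lgmn at -0.037 without the F1 5% D90 array. Target genes of PPAR-alpha, a receptor that induces fat oxidation, were higher in 13 of 22 (median +0.03). They included Fgf21 (+0.40 ± 0.13) and Acadl (+0.35 ± 0.29), whose other 2 probes had differences of -0.09 and -0.05. Without the F1 5% D90 array Acadl was at -0.024. Genes of cytosolic ribosomal proteins were higher in 32 of 49 (median +0.04; Rpl7a +0.50 ± 0.21, Rps7 +0.47 ± 0.38), and without the F1 5% D90 array Rps7 was at -0.05. Circadian genes were lower in 12 of 18 (median -0.12; Usp2 -0.39 ± 0.17, Tef -0.34 ± 0.13). None of these 9 lists had a member that passed by limma when adjusted over the list alone, and the adjusted p = 0.778 for each with an estimated correlation.

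By limma 0 genes passed for generation, with 191 at an unadjusted p below 0.05, and 10.1% of genes had the same sign in all 4 pairs, where chance gives 12.5%. Of 44 lists 9 passed (7 higher, 2 lower) and none with an estimated correlation (smallest adjusted p = 0.778). None of the 9 passed in each of the 8 fits without 1 array. The highest adjusted p was 0.994 for ribosomal proteins (without F1 5% D90), 0.538 for macrophage markers (without F3 21% D90), 0.432 for PPAR-alpha targets (without F1 21% D90), 0.343 for circadian genes (without F1 21% D456), 0.302 for MHC class II (without F3 21% D90), 0.243 for proteasome (without F3 21% D456) and 0.0944 for cell cycle (without F1 5% D90). The medians of all 9 lists moved by more than 1.5 times in at least 1 fit. They ranged from 0.0012 (without F1 5% D90) to 0.0796 for ribosomal proteins, from 0.0206 (without F3 21% D90) to 0.137 for MHC class II, from 0.0226 (without F1 5% D90) to 0.0799 for cell cycle and from 0.033 (without F1 21% D90) to 0.0815 for proteasome. Circadian genes ranged from -0.175 (without F1 5% D456) to -0.0493 (without F1 21% D456), PPAR-alpha targets from -0.0304 (without F1 5% D456) to 0.113 (without F1 5% D90) and macrophage markers from -0.0157 (without F3 21% D90) to 0.159 (without F1 5% D456). Pancreas markers reached 1.07 without F1 21% D90.

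Whether 1 factor acted differently across another was tested with interaction terms. For diet by age the smallest p-values belonged to Cela1 (-1.98 ± 0.30), Klk1b27 (-0.78 ± 0.12) and Gp2 (-1.15 ± 0.18, adjusted p = 0.327 for each). Cela1, another pancreatic elastase, had a diet difference of -1.51 at day 456 and a mean of +0.47 at day 90, where it was +0.96 in F1 and -0.03 in F3. That of Gp2 was +0.08 in F1 and -0.54 in F3 at day 90, and -1.20 and -1.55 at day 456. Klk1b27 had -0.01, -0.29, -0.78 and -1.09, in the same order. In all 3 genes the difference was most negative where the array of the 5% diet held most pancreas transcripts. Whether carried-over pancreas accounts for these interactions was not tested. For diet by generation they belonged to Corin (+0.68 ± 0.14), the neutrophil chemokine gene Cxcl1 (-0.99 ± 0.24) and Fbp2 (+0.21 ± 0.05, adjusted p = 0.9998 for each). For age by generation they belonged to the mitotic spindle gene Nusap1 (-0.37 ± 0.05), D17H6S56E-5 (-0.43 ± 0.07) and the glutathione transferase gene Gsta2 (-1.22 ± 0.19, adjusted p = 0.969 for each). Gsta2 had an age difference of +0.32 in F1 and of -0.90 in F3. By limma 0 genes passed for each interaction, with 1055, 105 and 260 at an unadjusted p below 0.05. Without F3 5% D90, the F1 5% D90 array alone stood for the 5% diet at day 90. That array stood apart from the rest and lacked the pancreas transcripts that the arrays of the 5% diet at day 456 held. The count of that fit, given next for diet by age, therefore does not show an interaction of diet and age. Leaving out 1 array gave up to 232 genes for diet by age (without F3 5% D90, with 11 without F3 21% D90 and 4 without F3 5% D456), 8 for diet by generation (without F1 21% D456, with 3 without F1 5% D90) and 12 for age by generation (without F1 5% D90, with 2 without F1 21% D456).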

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

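The tests of the 5% diet alone, of carried-over tissue in the F1 5% D90 array, of the combination itself, of the share of hepatocytes and of blood were chosen after the result was seen, while the pancreas ratio test, the second probe test and the splits of the arrays were chosen before.

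Pancreatic enzyme transcripts stood in 3 of the 4 arrays of the 5% diet, with medians that lay apart from the other arrays of their groups: 8.88 in F3 5% D90 among the arrays of day 90, and 9.51 in F1 5% D456 among the F1 arrays. If pancreas tissue was carried over, all its transcripts should come in 1 ratio, and the log2 ratio of the excess between the raised arrays had an SD of 0.417 or less over 21 markers, which is consistent with carry-over of pancreas. The excess in F3 5% D90 was 28.6% and in F1 5% D456 58.3% of that in F3 5% D456. The F1 5% D90 array, with a median of 6.87, lacked these transcripts, but that is part of the pattern and rests on 1 array, so it decides nothing about the 5% diet as the cause. The diet and carry-over of pancreas cannot be told apart by it, and an effect of the diet stays open and was not tested.

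The F1 5% D90 array stood apart from the other 7. Of its 125 genes that deviated by 1 or more on the log2 scale, 87.2% were lower there. Muscle transcripts were among the 16 that were higher. The lower genes included pancreas markers, which looked low because other arrays held pancreas transcripts. Cela2a deviated by -1.77, although its 7.55 lay within the 7.54 to 12.08 of the other 7. The share was not counted without such genes, so it does not decide on carried-over tissue as the source of the whole pattern. Some lower genes lay below all other arrays, such as Glud1 (9.39 against 11.16 to 11.86). Errors of single probes and the combination of diet, age and generation itself cannot be told apart: second probes moved the same way in 75.9% of 54 genes, between the bounds set for either reading, and the mean correlation of 0.977 comes from the only array of that combination. In the other arrays second probes moved the same way in 100% of 2 to 8 genes.

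Immune cell markers were higher at day 456, and a lower share of hepatocytes would raise markers of every other cell type alike, but macrophage markers exceeded endothelial markers in 4 of 4 pairs, by a mean of 0.21 (SD 0.15), which argues against it as the whole cause. Red blood cell markers were higher in every pair, by 0.14 or more, as blood left in the tissue would give. That rise had been seen when the test was chosen, so the test does not decide whether blood accounts for the neutrophil markers. In F1 21% D90 the neutrophil median was 7.33, against 7.11 to 7.13 in the other arrays of day 90. Red blood cell markers had 7.64 there, inside the 7.54 to 7.68 of those arrays. Markers of tissue macrophages, which blood lacks, were higher in 4 of 4 pairs, by a mean of 0.33 (SD 0.23) and by 0.098 in the lowest pair. That pair lay below the 0.1 set as the bound, so for the macrophage markers blood and a change in the tissue cannot be told apart. A change with age itself stays open as an untested explanation.

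Other splits of the 8 arrays into 4 and 4 were compared with the real one. The numbers of splits given below count the real one too. For the genes by age the real count was 9 and the highest other 28 (2 of 33 splits gave as many), so chance cannot be excluded. With a real count of 0 every split gives as many, so the splits test nothing for diet (highest other 0, 33 of 33), generation (20, 33 of 33) and each interaction (122, 32 of 32). For lists chance cannot be excluded either: the real count and the highest other were 13 and 19 for diet (11 of 33), 20 and 22 for age (6 of 33) and 9 and 18 for generation (27 of 33). The split with 122 genes set the 3 arrays with pancreas transcripts and the F1 21% D90 array against the rest, and that with 28 genes set F1 5% D90, F3 5% D90, F3 21% D90 and F3 21% D456 against the rest. For age a count several times the real one points to a structure of the samples, but whether 28 exceeds what noise and correlated genes give was not tested.

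Further values lay far from the other 3 arrays of a group of 4. Chance gives such a gap in about 1 in 20 groups, and 16 of 204 groups had one. For gene lists these were mitochondrial fatty acid oxidation in F1 5% D90 among the arrays of 5% fat (median 11.43, others 11.20 to 11.21), T cell and NK cell markers (7.17) and neutrophil markers (7.33) in F1 21% D90 among day 90, hepatocyte identity in F3 21% D456 among day 456 (12.503) and macrophage markers in F3 5% D90 among F3 (8.38). For genes they were Saa4 in F3 5% D90 among 5% fat (10.86), Gal3st1 in F3 21% D456 among 21% fat (7.31), Krt23 in F1 21% D456 (7.39) and Ccl21a in F3 21% D456 (7.76) among day 456, and Tnfrsf12a in F3 5% D90 among F3 (8.59). Among F1, the F1 5% D90 array lay apart for Rtn4 (6.99), Tbc1d16 (7.33), Cbx3 (7.06) and Pdk2 (8.34).

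Whether gene lists differed between groups was tested by the interaction itself. Of 132 tests 36 passed at the preset correlation, and the 8 given here also had an unadjusted p below 0.05 with an estimated correlation. None passed there after adjustment (smallest adjusted p = 0.193 by limma's camera). Chance alone gives such unadjusted values at a rate of 0.05, so several of 132 tests would meet that bound. For these 8 lists chance cannot be excluded. Their median interaction coefficients were -0.20 for MHC class II and -0.16 for macrophage markers (diet by age), -0.24 for gluconeogenesis and -0.10 for insulin and growth hormone signalling (diet by generation), and -0.39 for fatty acid synthesis, -0.49 for cholesterol synthesis, -0.32 for drug metabolism and -0.14 for cell cycle genes (age by generation). Fatty acid synthesis genes had a median age difference of +0.24 in F1 and -0.15 in F3, and cholesterol synthesis genes of +0.41 in F1 and -0.02 in F3.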

How the results depend on the processing

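Tests with background subtraction, array weights and the pancreas covariate were chosen after the result was seen. Genes differing by age numbered 9, and 25 without a filter, 2 with a stricter filter, 0 without a variance trend, 24 with robust variance, 52 at an adjusted p below 0.10, 24 with the factor alone, 15 with background subtracted, 234 with array weights and 27 with the pancreas covariate. With all 2-way interactions, which left 1 residual degree of freedom, 109 genes passed for diet, 461 for age and 54 for generation, and 161, 39 and 51 for the interactions diet by age, diet by generation and age by generation. Genes differing by diet numbered 43 with array weights and 44 with the pancreas covariate. Lists differing by diet, age and generation numbered 0 each with an estimated correlation and with fry, those by age 13 with the stricter filter and those by diet 4 with the pancreas covariate. The stricter filter tested fewer genes; for the other changes the cause was not tested. Other scalings, the floor, ways to combine probes, the 1.5-fold minimum and the matched-pair block kept the count of genes for age within 1.5 times (6 to 13). Leaving out 1 array gave 0 to 30 genes for diet, 0 to 23 for age, 0 to 232 for diet by age, 0 to 8 for diet by generation and 0 to 12 for age by generation. Of the values of named genes and lists under all alternatives, 2943 and 755 kept their direction and their side of the threshold. For genes 225 passed only under the alternative, 55 passed no longer and 18 reversed, and for lists 194 passed no longer and 9 reversed. The 2943 include genes that passed in neither fit. Only a gene that passed could be lost, so all 55 losses fell on the 9 genes for age. Ces3b lost its call in 10 fits and kept it in 12, Cyp1a2 lost it in 9 and kept it in 13. Csprs lost it in 4 and kept it in 18.

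With the pancreas covariate these turned: for diet Ccl5 (0.0598), Cela2a (0.0749), Amy2a5 (0.0605), Hsph1 (-0.60), Psmd13 (-0.0896) and the lists of heat shock proteins (-0.10), gluconeogenesis (-0.0605), MHC class II (-0.0034) and pancreas markers (-0.0577), of which gluconeogenesis, MHC class II and pancreas markers turned in the direction of the list test while their medians kept their sign; for age Cela2a (-0.0900), Asl (-0.0942), Atp5pb (-0.14), Rps6 (-0.10), Rps7 (-0.21) and the lists of respiratory chain (-0.0104) and ribosomal proteins (-0.0044); for generation Acadl (-0.0568), Lgmn (-0.0941), Rps7 (-0.0591) and the lists of pancreas markers (-0.0038) and ribosomal proteins (-0.0068). The covariate removes pancreas signal by construction; for the others the cause was not tested. Without 1 array the ranges were -0.0104 to 0.94 for Hsd3b5 by diet and, for generation, -0.0237 to 0.61 for Acadl, -0.81 to 0.0355 for Cyp4a12a, -0.0371 to 0.43 for Lgmn, -0.0502 to 0.82 for Rps7, -0.0157 to 0.159 for macrophage markers, -0.0304 to 0.113 for PPAR-alpha targets and -0.42 to -0.00077 for male-biased genes. The last turned only in the direction of the list test, while for macrophage markers and PPAR-alpha targets the median changed sign and the direction of the test did not.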

Other observations

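The test of male RNA below was chosen after the result was seen, and so were the genes named in this part. Acute phase proteins, which the liver secretes in inflammation, were read in each array. In the F1 21% D90 array the serum amyloid genes Saa1, Saa2 and Saa3 stood at log2 intensities of 9.46, 9.25 and 10.62, and the orosomucoid gene Orm2 at 12.05. In the F3 21% D456 array Saa1 (9.08) and Saa2 (8.75) were high as well, while Saa3 was at 8.65. The other 6 arrays had Saa1 between 7.15 and 8.06 and Saa2 between 7.11 and 7.96. Orm2 was at 11.76 and Lcn2 at 11.89 in F3 21% D456, and other arrays of day 456 had Orm2 up to 11.23 and Lcn2 up to 10.90. By limma Saa1, Saa2, Saa3, Orm2 and Lcn2 did not pass for any factor (smallest adjusted p = 0.365, Lcn2 by age).

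Genes of stomach mucosa appeared in the F1 5% D456 array, which also held pancreas transcripts. Tff2, a trefoil peptide of gastric mucus, stood at a log2 intensity of 11.002 there, at 8.59 in F3 5% D456 and at 7.71 or less in the other arrays. Gkn3, another gastric gene, stood at 8.75 in F1 5% D456 and at 6.94 or less elsewhere. Ins2, an insulin gene of pancreatic islets, had an intensity of 143.9 in F1 5% D456 and of 132.2 in F3 5% D456, against 112.8 to 117.4 in the other 6 arrays.

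Male-biased liver genes were highest in the F1 21% D90 array, where Cyp4a12a stood at a log2 intensity of 9.11 against 6.87 to 6.92 in the other 7 arrays, and Hsd3b5 at 10.39. The labels name females. RNA of a male animal beside female RNA in that array, as in a pool, may account for this. The Y-linked gene Eif2s3y was 0.55 above the highest of the other 7 arrays on the log2 scale, where those 7 spanned 0.05. Xist was at 8.10 in that array and at 7.98 to 8.63 in the others, so female RNA was present too. Another Y-linked gene, Kdm5d, had an intensity of 122.0 there and of 115.8 to 118.8 elsewhere, and Uty did not stand out (122.7 against 121.6 to 128.6). Without that array the male-biased genes had a median of -0.29 by age (adjusted p = 0.00279 at the preset correlation; with all arrays the adjusted p = 0.456 with an estimated correlation), while their differences by diet (+0.03) and generation (-0.00077) no longer passed.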
